A study of Mus musculus with 6 samples.

How the data were processed

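Gene expression was measured in cultured kidneys of CD1 mouse embryos on 6 arrays, with RNA of Scriptaid-treated and of Nullscript-treated kidneys in the 2 channels of each array. The groups are the 3 arrays with Scriptaid labelled in Cy3 and the 3 with Scriptaid labelled in Cy5, and the channel of each drug was taken from the source name and dye fields of the array. The labels number 3 biological replicates and, per the labels' treatment protocol, paired kidneys received the different drugs. How many embryos or litters make up a replicate is not given in the sources used here.

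The deposited scanner files give the intensity of each spot and of its local background in both channels, per the file headers from Agilent Feature Extraction 9.1.3.1, together with processed intensities that the software had background-corrected, detrended and dye-normalised. The scanner files also hold the deposited log10 ratio of Cy5 over Cy3, per the file headers. The series value table holds log10 ratios deposited by the authors for the same spots. Set against the scanner ratios, each of its columns equals the log10 ratio of the channel labelled Scriptaid over the channel labelled Nullscript, with differences of at most 4.82e-06, and no further centring. The column medians on the log10 scale lay between -0.00959 and -0.00136.

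Mean intensities were background-corrected with normexp (offset 50) and normalised within each array by loess in limma 3.58.1 (R 4.3.3), with control spots at weight 0. Spots with an outlier mark of the software were left out, saturated spots were kept, and spots of the same probe were averaged. The sign of each array was set so that ratios read labelled Scriptaid over labelled Nullscript. The 2 arrays of a replicate were averaged, which cancels a dye effect of equal size on both. The 26 genes saturated in both channels of all arrays had means that do not cancel. These were -1.44 with Scriptaid labelled in Cy5 and 0.41 with Scriptaid labelled in Cy3. A probe entered the test if it was well above background on at least 3 of 6 arrays for either drug, which left 39407 probes. A gene with several probes is represented by the brightest. Of 41174 probes, 22951 were named through their accession in the reference gene table, 6659 through a current symbol and 3109 through an older symbol, and 8455 kept the name of the array file. Of the 26499 genes tested, 19208 are in that table.

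The mean of the 3 replicates was tested against 0 with lmFit and eBayes, and p values were adjusted by Benjamini-Hochberg over genes. The 25 gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists, and counts of members were also adjusted over the list alone. None of the 19 list calls held with a correlation estimated from the data, where the lowest adjusted p was 0.290. That test also missed a simulated list shifted by 0.5 with independent noise (adjusted p = 0.106). The list of genes that rise with HDAC inhibitors in other cells had an estimated correlation of -0.03, below the preset. Its camera p still went from 0.000104 to 0.0558. Not passing with an estimated correlation therefore does not show that a list was unshifted. The lists cover nephron progenitors, ureteric bud, renal vesicle, podocytes, proximal tubule, stroma, endothelium, red blood cells, macrophages, neuronal genes, drug response, HDACs, kinase inhibitors, p53, cell cycle, apoptosis, Wnt, Ret and FGF, Notch, renin-angiotensin, stress, hypoxia and ribosomal proteins. The lists, the fits and the rule for named genes were fixed before the data were examined. The rule takes, per direction, the 12 genes with a proper symbol and the largest absolute log2 ratio among those that passed with the same sign in all 3 replicates. It adds per list up to 4 members with the largest ratios among those that passed, or the 2 brightest where none passed, and 16 genes fixed by name. Of the latter, Osr1, Eya1, Pax2, Pax8, Wt1, Gdnf, Wnt9b, Sfrp1, Sfrp2, Emx2, Six2 and Lhx1 were taken as genes the study is known to discuss. Their choice is therefore not independent of the study. Some genes that the rule takes are not reported here. Cd68, Adgre1, Nphs1 and Rpl14 fall outside the rule and were chosen after their values were seen.

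For a gene not well above background in 1 channel on any array, the bound sets the mean of the brighter channel against the lowest signal among probes well above background, or the dim probe's own signal where higher, after loess and Aquantile. The dye effect was fitted on the 6 arrays with the replicate as a block, for which the consensus correlation was 0.119. The labels state that the 2 arrays of a replicate are the same biological replicate. The deviations of these arrays from the mean of their dye orientation correlated at 0.61, 0.15 and -0.03 in replicates 1, 2 and 3. Between arrays of different replicates they correlated at -0.39 to 0.21, a range that only the value of replicate 1 exceeded. On simulated arrays with the residual spread and dye coefficients of the real ones, with 200 of 26424 genes changed, the fit recovered 97.0% of genes changed by 1 on the log2 scale, 77.6% of those changed by 0.5 and 25.4% of those changed by 0.25, and 0.746% of its calls were false. These shares hold for few changed genes and independent noise, while 46.3% of the real genes passed. They therefore do not give the recovery or the false share of the real calls. A simulated list of 15 genes shifted by 0.5 passed with the preset correlation and had an adjusted p of 0.106 with an estimated correlation. The simulated noise was independent between genes, while the estimated correlations of the real lists ran from -0.10 to 0.54. The simulation therefore cannot show whether the preset correlation suits the real lists.

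Per array, the median intensity was between 9.66 and 20.6 times the median background. The precision is limited by the number of arrays. Alternatives were median centring with no loess, Aquantile after loess, the processed intensities, the deposited log10 ratios, no background subtraction, an offset of 16, no filter, a stricter filter, 6 arrays with a replicate block, each dye orientation alone, a trended robust eBayes, the mean over probes, leaving out each replicate, a slide block, camera with an estimated correlation, fry, and stricter thresholds. Leaving out saturated probes was added after seeing the data. A spike-in reference was not used, since the ratios of the spike-in probes spanned only -0.06 to 0.01 and neither a spike-in mix nor an amount is given in the sources used here. Figures were drawn with matplotlib 3.10.9.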

Results

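Kidneys of E13.5 CD1 mouse embryos were grown as explants on filters and treated for 6 hours with Scriptaid or with Nullscript, each at 2.0 µg/ml. Scriptaid is a hydroxamic acid that inhibits histone deacetylases (HDACs), the enzymes that remove acetyl groups from histones and other proteins. Nullscript is a structural relative of Scriptaid that serves as its inactive control. Total RNA of both treatments was labelled with Cy3 or Cy5 and hybridised together to 2-colour Agilent 4x44k arrays. The 3 biological replicates were each measured on 2 arrays with the dyes exchanged, which gave 6 arrays, 3 with Scriptaid labelled in Cy3 and 3 with Scriptaid labelled in Cy5. The series text speaks of a dye swap on 2 of 4 arrays, and the dye fields of the 6 arrays were followed here. Each array held 45018 spots, 43379 of them other than control spots. Of these 43379, between 91.5% and 96.5% per channel were well above background. After the sign of swapped arrays was turned, the log2 ratios were correlated over the probes that passed the background filter. They correlated between 0.75 and 0.86 for the 2 arrays of a replicate and between 0.87 and 0.94 for arrays of different replicates with the same dyes. For arrays of different replicates with the dyes exchanged they correlated between 0.73 and 0.83. These correlations run across probes, which are not independent replicates, and the 3 replicates limit the precision of every value.

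The comparison asks which embryonic kidney genes differ in expression between an HDAC inhibitor and its inactive relative after 6 hours. Of 26499 genes tested, 5966 were higher in the channel labelled Scriptaid and 6290 were higher in the channel labelled Nullscript at a limma adjusted p under 0.05, together 46.3% of the genes. The direction of these counts is not settled. By the dye fields of the arrays, genes known to rise with HDAC inhibitors in other cells were higher with Nullscript. The array titles name the drug of the Cy3 channel first, and the deposited ratios follow the dye fields. Ratios are therefore given as log2 of the channel labelled Scriptaid over the channel labelled Nullscript throughout. If the drug names were exchanged, every sign would turn and the counts would become 6290 higher and 5966 lower with Scriptaid.

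Most differences were small. The median absolute log2 ratio of the genes that passed the test was 0.35, and 9362 of these 12256 genes differed by less than 1.5-fold. At least 2-fold differences were found for 449 genes higher in the channel labelled Scriptaid and 355 higher in the channel labelled Nullscript. All 3 replicates had the same sign for every gene that passed and had a value in each. On the arrays with Scriptaid labelled in Cy3 alone, 9362 of the 12256 genes passed in the same direction and 206 in the other, and on those with Scriptaid labelled in Cy5 alone 10373 and 6. Replicates 1 and 2 shared a slide and replicate 3 was on another. With the slide as a block 5019 and 4932 genes passed, and replicates 1 and 2 alone (without replicate 3) gave 4329 and 4002. Of the genes called within the first slide, 99.9% had the same sign on the second. For called genes with further probes, 84.6% of those probes had the same sign.

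The HDAC inhibitor response genes fixed from other cell types lay on the sides opposite to the labels. Of 10 genes that rise in other cells, 9 were higher in the channel labelled Nullscript and 1 in the channel labelled Scriptaid, the same numbers as adjusted over the list alone (camera adjusted p = 0.000372, and adjusted p = 0.290 with an estimated correlation). H1f2, a linker histone, had a log2 ratio of -1.72 ± 0.06 (SD, n = 3), and H1f0, the linker histone of resting cells, was 2.00-fold higher in the channel labelled Nullscript, with -0.82 and -0.80 by its other probes. Gsn, which severs actin filaments, had -1.04 ± 0.14 and Txnip, an inhibitor of thioredoxin, -1.01 ± 0.08. Histone genes have near-identical copies, and a probe can take signal from more than 1 of them. Of 7 genes that fall in other cells, 6 were higher in the channel labelled Scriptaid and none in the other, also adjusted over the list alone (camera adjusted p = 0.000887, and adjusted p = 0.290 with an estimated correlation). Ccnd1, the G1 cyclin D1, had 1.90 ± 0.19, Myc 1.71 ± 0.28 with 0.30 to 1.76 by other probes, Tyms, which makes thymidylate, 0.73 ± 0.03 with -0.02 to 0.74 by other probes, and Ccnb1, a mitotic cyclin, 0.59 ± 0.12. All 8 genes named here had limma adjusted p values of 0.000847 or lower.

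Cyclin-dependent kinase inhibitors lay on the side of the linker histones, and Cdkn1a is also in the list of genes that rise in other cells. Of 7 measured, 6 were higher in the channel labelled Nullscript, and adjusted over the list alone 6 and 1 in the other direction (camera adjusted p = 0.00645, and adjusted p = 0.290 with an estimated correlation). Cdkn2b had a log2 ratio of -1.43 ± 0.06 (SD, n = 3), Cdkn1a, the p21 inhibitor, -0.91 ± 0.16, and Cdkn2d -0.75 ± 0.09. Cdkn1c, which counts among the 6, was saturated on 3 arrays in each channel, so no ratio over all arrays is given, and it turned to 0.17 (limma adjusted p = 0.0421) on the arrays with Scriptaid labelled in Cy3 alone. Cell cycle genes lay on the other side, and Tyms, Top2a and Ccnb1 are also in the list of genes that fall in other cells. In the S phase list, 12 of 22 genes were higher in the channel labelled Scriptaid and 5 in the channel labelled Nullscript, against 13 and 5 adjusted over the list alone (camera adjusted p = 0.00279, and adjusted p = 0.290 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, had 1.13 ± 0.24, Rrm1 0.65 ± 0.07 and the replication helicase gene Mcm7 0.65 ± 0.09. For G2 and mitosis, 16 of 21 were higher in the channel labelled Scriptaid and 1 in the other, also adjusted over the list alone (camera adjusted p = 4.53e-05, and adjusted p = 0.290 with an estimated correlation). Plk1, a mitotic kinase, had 0.83 ± 0.07, and Cdc20, saturated in the channel labelled Scriptaid on 1 array, passed in the same direction. Cenpa had 0.96 ± 0.05 by its brightest probe and 0.00 by another, and Nusap1 0.76 ± 0.14 and -0.12. The p53 target list did not pass (camera adjusted p = 0.191), with 2 of 20 genes higher in the channel labelled Scriptaid and 7 in the channel labelled Nullscript, also adjusted over the list alone. Its members Pmaip1, which encodes the cell death protein Noxa, and Gadd45a had -1.33 ± 0.12 and -0.58 ± 0.14, and Phlda3 had 0.82 ± 0.15.

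**Figure D1:**
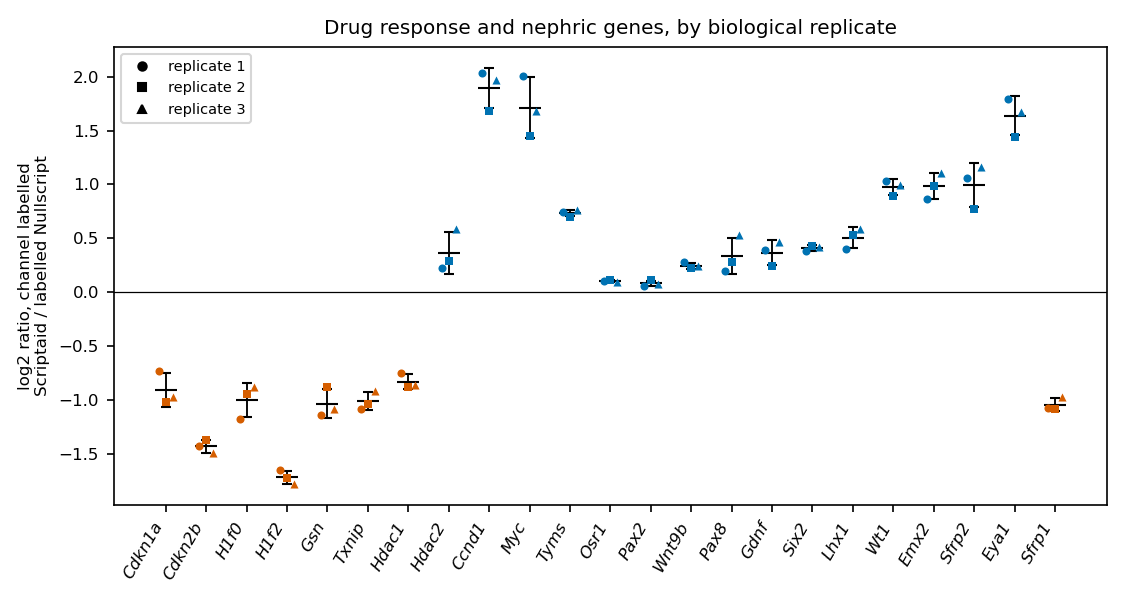
Log2 ratio (vertical axis) of drug response genes and of nephric genes (horizontal axis) in each of the 3 biological replicates, with the mean (bar) and SD (whiskers). Cdkn1a, at -0.91, and the linker histones lie below 0, while Wt1, at 0.97, and Eya1, at 1.64, lie above it in all 3 replicates.

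The HDAC genes did not shift as a list (camera adjusted p = 0.925). Of 11 measured, 4 were higher in each channel, also adjusted over the list alone. Hdac1 was higher in the channel labelled Nullscript, with a log2 ratio of -0.83 ± 0.07 (SD, n = 3), as was Hdac5, with -0.43 ± 0.04. Hdac10, at 0.49 ± 0.09 with 0.27 by its other probe, and Hdac8, at 0.48 ± 0.14 with 0.09 by its other probe, were higher in the channel labelled Scriptaid. Hdac2 had 0.37 ± 0.20 (limma adjusted p = 0.0149) and 0.06 by its other probe, and did not pass on the arrays with Scriptaid labelled in Cy3 alone (adjusted p = 0.0540).

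Genes of the nephron lineage were mostly higher in the channel labelled Scriptaid. Of 17 nephron progenitor genes, 13 were higher there and 3 in the channel labelled Nullscript, against 14 and 3 adjusted over the list alone (camera adjusted p = 0.000275, and adjusted p = 0.290 with an estimated correlation). Eya1, a transcription cofactor that nephron progenitors need, had a log2 ratio of 1.64 ± 0.18 (SD, n = 3), which is 3.11-fold, and 0.48 by its other probe. Crym had 1.32 ± 0.13, the homeobox genes Meox1 and Hoxa11 1.20 ± 0.17 and 1.12 ± 0.29, Meox1 with 0.79 by its other probe, and Wt1, the transcription factor gene of Wilms tumour, 0.97 ± 0.07. Six2, the transcription factor gene of self-renewing progenitors, had 0.41 ± 0.02 and Gdnf, the growth factor gene that draws out the ureteric bud, 0.37 ± 0.11. Osr1, an early kidney lineage gene, had 0.10 ± 0.01 (limma adjusted p = 0.0305) and 0.83 by its other probe. Its ratio stayed at 0.10 to 0.11 without each replicate in turn, but its call was lost, with adjusted p values of 0.0773, 0.107 and 0.156 without replicates 1, 2 and 3. Pax2, at 0.08 ± 0.03, did not pass (limma adjusted p = 0.0761). In the renal vesicle list, 12 of 17 genes were higher in the channel labelled Scriptaid and none in the other, against 13 and 0 adjusted over the list alone (camera adjusted p = 7.77e-05, and adjusted p = 0.290 with an estimated correlation). Wnt4, the signal for nephron epithelium to form, had 0.90 ± 0.18, the matrix gene Npnt 0.70 ± 0.18 with 0.42 to 0.48 by other probes, the Notch ligand gene Dll1 0.63 ± 0.03, Heyl 0.53 ± 0.02 and Lhx1 0.51 ± 0.09. Pax8 had 0.34 ± 0.17 and -0.03 by its other probe.

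In the ureteric bud list, 9 of 18 genes were higher in the channel labelled Scriptaid and 2 in the channel labelled Nullscript, against 11 and 2 adjusted over the list alone (camera adjusted p = 0.00559, and adjusted p = 0.290 with an estimated correlation). Emx2, a homeobox gene of the bud, had a log2 ratio of 0.98 ± 0.12 (SD, n = 3), Gata3 0.78 ± 0.10, Cldn3 0.63 ± 0.09 and Wnt9b, a bud signal to the mesenchyme, 0.25 ± 0.03, while Cdh1, the epithelial cadherin, had -0.68 ± 0.06. For podocytes, 7 of 15 genes were higher in the channel labelled Scriptaid and 2 in the other, against 8 and 2 adjusted over the list alone (camera adjusted p = 0.0353, and adjusted p = 0.290 with an estimated correlation). That call was also lost without replicate 2 (adjusted p = 0.0690) and on the arrays with Scriptaid labelled in Cy5 alone (adjusted p = 0.0584). Dach1 had 0.86 ± 0.10 with 0.38 by its other probe and Magi2 0.56 ± 0.10, while Ptpro, at 0.78 ± 0.10, and Kirrel, at 0.60 ± 0.20, had other probes at -0.08 and 0.08. The slit diaphragm gene Nphs1, at 0.06, did not pass. The proximal tubule list did not pass (camera adjusted p = 0.0580), with 7 of 14 genes higher in the channel labelled Scriptaid and 2 in the other, against 9 and 2 adjusted over the list alone. It passed without replicate 3 (adjusted p = 0.0496) and with the mean over all probes of a gene (adjusted p = 0.0269). Its members Pdzk1, Cubn and Aqp1 had ratios of 0.57 ± 0.11, 0.46 ± 0.13 and 0.40 ± 0.13.

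Stromal and endothelial genes shifted the same way. In the stromal list, 13 of 17 genes were higher in the channel labelled Scriptaid and 2 in the channel labelled Nullscript, against 13 and 3 adjusted over the list alone (camera adjusted p = 0.000896, and adjusted p = 0.290 with an estimated correlation). Lum, a matrix proteoglycan, had a log2 ratio of 1.71 ± 0.17 (SD, n = 3), the transcription factor gene Tcf21 1.69 ± 0.20 and Pdgfra 0.86 ± 0.17, with 0.12 by its other probe. Sfrp1, a secreted Wnt antagonist, went the other way at -1.04 ± 0.06. Of 16 endothelial genes, 13 were higher in the channel labelled Scriptaid and 2 in the other, also adjusted over the list alone (camera adjusted p = 0.000161, and adjusted p = 0.290 with an estimated correlation). Ramp2, a receptor partner for adrenomedullin, had 1.80 ± 0.19, the transcription factor gene Sox7 1.78 ± 0.40 with 0.40 by its other probe, Icam2 1.47 ± 0.29 and Esam 1.07 ± 0.21.

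Markers of blood cells and neurons were also measured. In the macrophage and leukocyte list, 9 of 16 genes were higher in the channel labelled Scriptaid and 3 in the channel labelled Nullscript, also adjusted over the list alone (camera adjusted p = 0.00519, and adjusted p = 0.290 with an estimated correlation). The lysozyme genes Lyz1 and Lyz2, which are near-identical copies, had log2 ratios of 0.94 ± 0.18 and 0.89 ± 0.07 (SD, n = 3), Lyz2 with 0.18 by its other probe, and Cd14 had 0.59 ± 0.12. Ptprc, the common leukocyte antigen, had 1.07 ± 0.12 by its brightest probe and between -0.11 and 0.15 by others, and the macrophage genes Cd68 and Adgre1, at 0.03 and 0.06, did not pass. Of 12 red blood cell genes, 5 were higher in the channel labelled Nullscript and none in the other, also adjusted over the list alone (camera adjusted p = 0.0353, and adjusted p = 0.290 with an estimated correlation). This call was lost under 9 of 21 alternatives, among them without replicate 2 (adjusted p = 0.0731). Hbb-bh1 and Hbb-y, embryonic globin genes with near-identical relatives, had -0.31 ± 0.02 and -0.30 ± 0.08, and the globin genes Hba-a1 and Hbb-bt, which count among the 5, were saturated on some arrays and turned to 0.33 and 0.25 on the arrays with Scriptaid labelled in Cy3 alone. In the neuronal list, 11 of 20 genes were higher in the channel labelled Nullscript and 2 in the other, against 12 and 2 adjusted over the list alone (camera adjusted p = 0.00178, and adjusted p = 0.290 with an estimated correlation). Nefm, a neurofilament gene, had -1.33 ± 0.18 and -0.14 by its other probe, Stmn2 -1.16 ± 0.07 and -0.19, and the synaptic gene Snap25 -0.74 ± 0.09 and between -0.78 and -0.06, while Elavl4, a neuronal RNA-binding protein gene, had 1.29 ± 0.14 and 0.71 by its other probe.

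**Figure D2:**
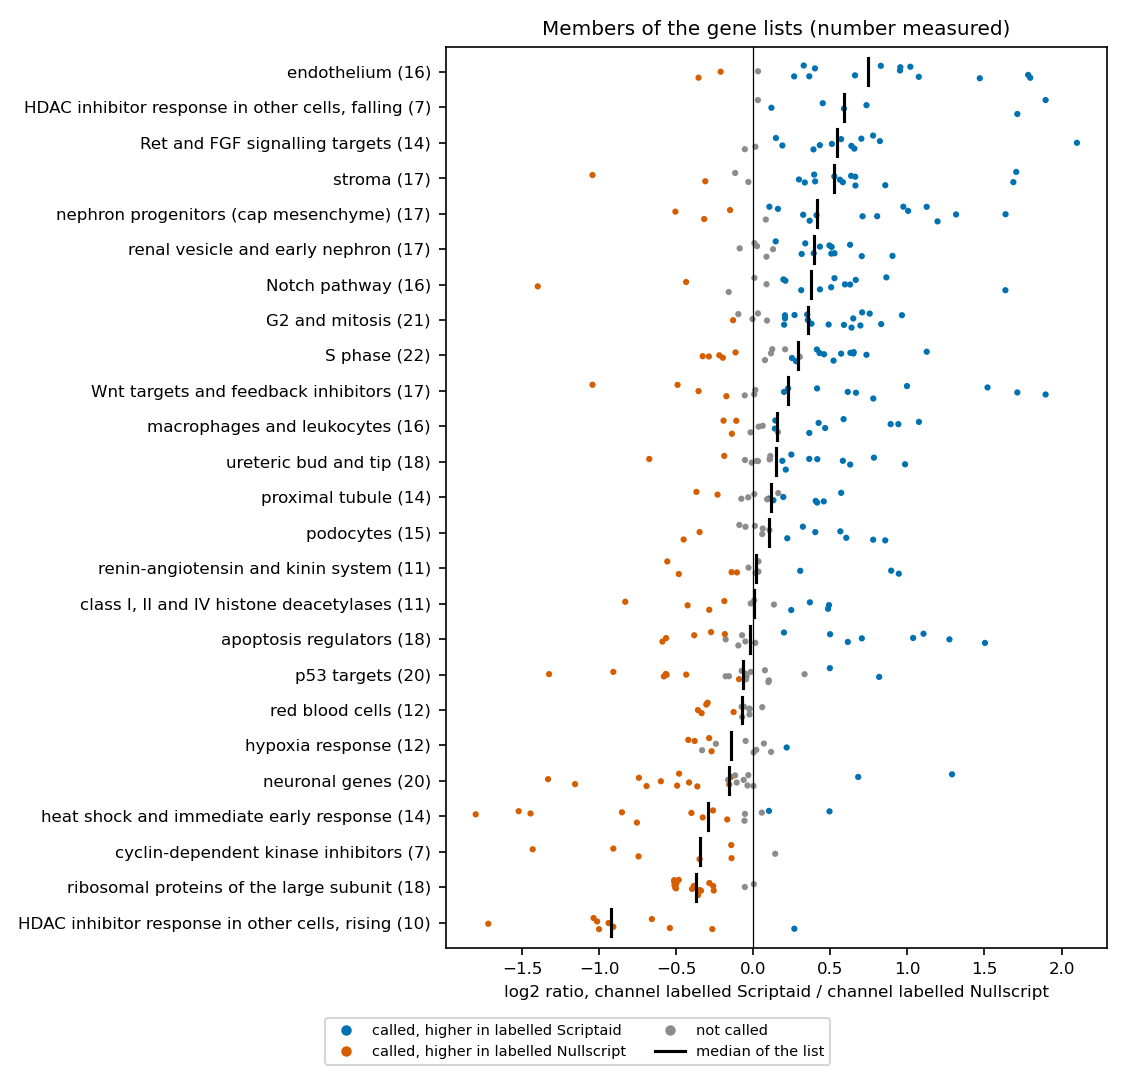
Log2 ratio (horizontal axis) of each measured member (point) of the 25 gene lists (rows), with the median of each list as a bar and colours for members that passed the limma test. The medians run from -0.92 for genes that rise with HDAC inhibitors in other cells to 0.74 for endothelial genes.

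Signalling genes of kidney development lay mainly with the nephron genes, although the lists share members. Jag1, Dll1, Lfng and Heyl of the Notch list are also in the renal vesicle list. Myb of the Ret and FGF list is also in the ureteric bud list. Of 14 Ret and FGF signalling targets, 12 were higher in the channel labelled Scriptaid and none in the other, also adjusted over the list alone (camera adjusted p = 4.53e-05, and adjusted p = 0.290 with an estimated correlation). Mmp14, a membrane matrix metalloproteinase, was saturated in the channel labelled Scriptaid on 3 arrays, and its other probe had a log2 ratio of 1.15. The transcription factor gene Etv1 had 0.82 ± 0.11 (SD, n = 3), Spred2, an inhibitor of the same pathway, 0.78 ± 0.16, and Cxcr4 0.70 ± 0.25 with 0.39 by its other probe. For the Notch pathway, 11 of 16 were higher in the channel labelled Scriptaid and 2 in the channel labelled Nullscript, against 11 and 3 adjusted over the list alone (camera adjusted p = 0.00218, and adjusted p = 0.290 with an estimated correlation). The receptor gene Notch4, at 1.64 ± 0.19, and the effector genes Hey1, at 0.86 ± 0.02, and Hes5, at 0.66 ± 0.15, went one way, and the ligand gene Jag2, at -1.40 ± 0.10, the other. In the list of Wnt targets and feedback inhibitors, 10 of 17 were higher in the channel labelled Scriptaid and 4 in the other, also adjusted over the list alone (camera adjusted p = 0.0283, and adjusted p = 0.290 with an estimated correlation). Dkk1, a secreted Wnt inhibitor, had 1.52 ± 0.16 and Sfrp2, a relative of Sfrp1, 1.00 ± 0.20, beside Ccnd1 and Myc. The Wnt call was lost on the arrays with Scriptaid labelled in Cy3 alone (adjusted p = 0.0617). The renin-angiotensin and kinin list did not pass (camera adjusted p = 0.925), with 3 of 11 genes higher in the channel labelled Scriptaid and 4 in the other, also adjusted over the list alone. In it the receptor genes Agtr2 and Agtr1a had 0.94 ± 0.30 and -0.56 ± 0.15, the latter with -0.09 by its other probe, and Atp6ap2, the prorenin receptor, had -0.48 ± 0.07.

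Of 14 heat shock and immediate early genes, 9 were higher in the channel labelled Nullscript and 2 in the channel labelled Scriptaid, also adjusted over the list alone (camera adjusted p = 0.0353, and adjusted p = 0.507 with an estimated correlation). The call was lost under 5 of 21 alternatives, among them with no loess (adjusted p = 0.195), with the deposited ratios (adjusted p = 0.0634) and on the arrays with Scriptaid labelled in Cy5 alone (adjusted p = 0.138). Hspa1a, a heat shock chaperone gene with a near-identical copy, had a log2 ratio of -1.80 ± 0.62 (SD, n = 3) with -1.85 to -0.74 by other probes, and the early response genes Fos, Egr1 and Atf3 had -1.52 ± 0.49, -1.45 ± 0.71 and -0.85 ± 0.11. Egr1 did not pass without replicate 3 (-1.51, limma adjusted p = 0.0534). The hypoxia list did not pass (camera adjusted p = 0.328), with 1 of 12 genes higher in the channel labelled Scriptaid and 4 in the other, also adjusted over the list alone. It passed without replicate 2 (adjusted p = 0.0488). Its members Bnip3 and P4ha1 had -0.29 ± 0.08 and -0.27 ± 0.19. Bnip3 did not pass on the arrays with Scriptaid labelled in Cy5 alone (-0.11, adjusted p = 0.138). P4ha1 did not pass without replicate 2 (-0.32, adjusted p = 0.0527) or without replicate 3 (-0.33, adjusted p = 0.0763). Without replicate 1 P4ha1 kept its call, but its ratio moved most, to -0.16. Pdk1 had -0.42 ± 0.24 and 0.11 by its other probe, and did not pass without replicate 3 (-0.43, adjusted p = 0.0880). The apoptosis list did not pass (camera adjusted p = 0.389), and its median of -0.02 and its mean of 0.25 differ in sign. It passed with median centring, no loess (mean 0.32). Of 18 members, 8 were higher in the channel labelled Scriptaid and 5 in the other, also adjusted over the list alone. The caspase gene Casp8 had a log2 ratio of 1.27 ± 0.22. Bak1, at 1.10 ± 0.07, and Birc3, at 1.04 ± 0.17, had other probes at -0.08 and 0.05.

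The brightest genes reached the ceiling of the scanner. Of 18 ribosomal protein genes of the large subunit, 16 were called higher in the channel labelled Nullscript and none in the other, also adjusted over the list alone (camera adjusted p = 4.53e-05, and adjusted p = 0.290 with an estimated correlation). Of the 18, 17 were saturated on at least 1 array, and Rpl8, Rpl13 and Rpl27 were saturated in both channels of all 6, so no fold is given for them. Rpl14, the only member never saturated by its brightest probe, had a log2 ratio of 0.00 ± 0.04 (SE, limma adjusted p = 0.964). Without saturated probes the list was not called (adjusted p = 0.521). The list's mean was -0.97 on the arrays with Scriptaid labelled in Cy5 and 0.24 on those with Scriptaid labelled in Cy3. Over all genes, 26 were saturated in both channels of all arrays, and all 26 passed the test as higher in the channel labelled Nullscript. Of the 569 genes saturated on at least 1 array, 373 were called higher in that channel and 94 in the other. Without saturated probes, 5939 genes were called higher in the channel labelled Scriptaid and 5967 in the channel labelled Nullscript.

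**Figure D3:**
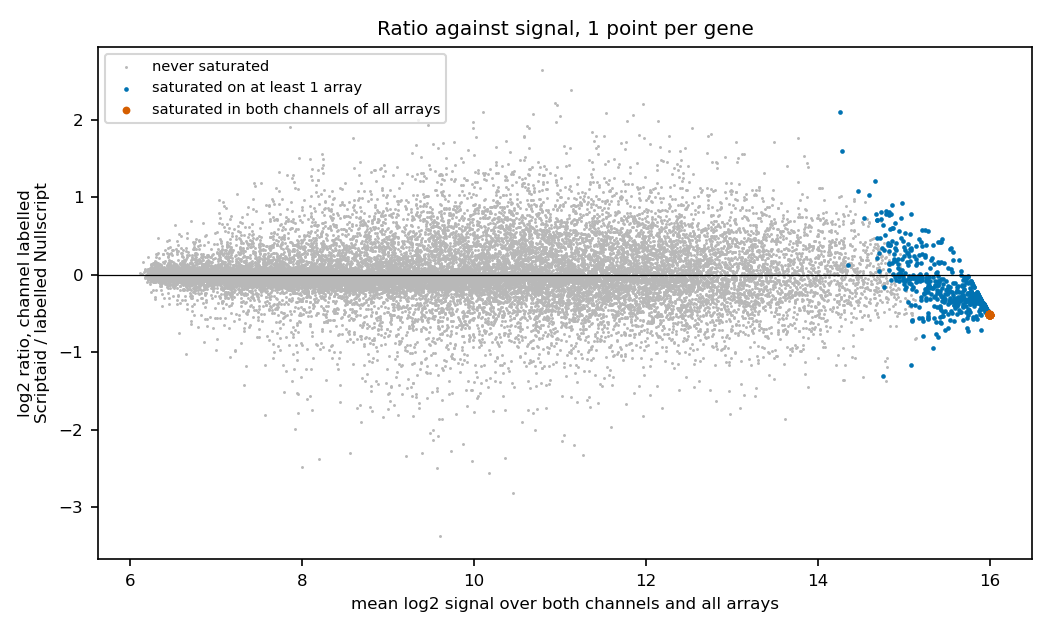
Log2 ratio of the channel labelled Scriptaid over the channel labelled Nullscript (vertical axis) against the mean log2 signal (horizontal axis) for each gene tested (point). The 26 genes saturated in both channels of all arrays sit together at the right edge, with a median of -0.51, and the 569 genes saturated on at least 1 array bend toward them.

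The 2 genes with the largest differences were higher in the channel labelled Nullscript. Dhh, a hedgehog signal known from testis and nerve, had a log2 ratio of -3.37 ± 0.17 (SD, n = 3), which is 10.3-fold. It was followed on that side by the secreted protease gene Htra1 with -2.82 ± 0.28, Plk5 with -2.56 ± 0.16, Ccdc184 with -2.50 ± 0.23, Isl2, a homeobox gene of motor neurons, with -2.49 ± 0.12, and the neuronal kinesin gene Kif5a with -2.41 ± 0.02 and -0.39 by its other probe. Pnpla3, Lrp11, Acbd7, Zcchc12 and Ankrd34b had ratios from -2.38 to -2.30. The limma adjusted p values of these 11 genes lay between 0.000111 and 0.000259. On the other side, the keratin gene Krt23 had 2.64 ± 0.24, which is 6.23-fold, the tendon transcription factor gene Scx 2.38 ± 0.17, the endothelial gene Esm1 2.22 ± 0.34 and the oxysterol hydroxylase gene Cyp7b1 2.11 ± 0.27. Tril had 2.21 ± 0.17 by its brightest probe and from 0.54 to 0.90 by others, Bend3 2.19 ± 0.20 and 0.01, and Has2, which makes hyaluronan, 2.09 ± 0.31 and 0.97. Cpped1, Lxn, Cebpd and Plpp5 had ratios from 2.00 to 2.08, and these 11 genes had adjusted p values between 0.000123 and 0.000274. The rule also takes Mmp14 there, by the saturated probe. A further 12 called genes were not well above background in 1 of the channels on any array, and the bounds ran from at least 1.03-fold to at least 1.34-fold.

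After loess, which removes the dye curve of each array, a smaller number of probes had a dye effect. In a limma fit on the 6 arrays with drug and dye as coefficients and the replicate as a block, 1505 probes, 3.82% of those tested, had a dye effect at an adjusted p under 0.05, with a median absolute dye coefficient over all probes of 0.05 on the log2 scale. The probes with a dye effect at adjusted p < 0.05 numbered 24155 with median centring, no loess, and 826 without probes saturated on any array. Among the drug response genes of other cells, all 16 called members had the same sign on the arrays of both dye orientations.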

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

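The tests of explanations in this part were chosen after the results were seen, although the fits they use without loess and on each dye orientation alone had been planned before. The viral E1A spike-in probes, which no comparison used, gave a signal above the negative controls. Of 10 such probe types, 8 were well above background in both channels of all 6 arrays. Over all 10 types the median intensity was 139 in Cy5 and 90.8 in Cy3, against 48.5 and 47.5 for the negative controls, and the median log2 ratios lay between -0.06 and 0.01. Between the 2 dye orientations, the turned ratio of 1505 probes differed in the limma fit. None of the 9 other splits of the 6 arrays into 3 and 3 gave any such probe (highest 0), but 10 splits are too few for a share under 0.05. The same holds for the 3 other splits that, like the real one, part the arrays of every replicate.

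The response genes of HDAC inhibitors lay on the sides opposite to the labels: 15 of the 16 called members of the 2 lists, 93.75%, were on the opposite side. Dye bias is argued against for the called members, because 100% of them kept their sign when the dyes were exchanged. They had been called on the mean of both orientations, which favours members that keep their sign. Top2a, which was not called, had -0.12 with Scriptaid labelled in Cy5 and 0.18 with Scriptaid labelled in Cy3. An exchange of the drug names in the dye fields of every array is a candidate explanation that has the values it needs. The authors' deposited ratios follow the dye fields on all 6 arrays, to within 4.82e-06, so it would have to reach those too. Ratios turned by the same fields would be no independent check, and the array titles name the drug of the Cy3 channel first. Read as Cy5 over Cy3, the titles would conflict with the dye fields on all 6 arrays. Read as Cy3 over Cy5, they follow those fields, so the titles do not settle the direction. A response of these kidneys opposite to that of other cells gives the same values and stays open, since 0 channels of the series hold neither drug. The direction of every result therefore remains unsettled.

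The ribosomal protein genes of the large subunit were called higher in the channel labelled Nullscript with a mean log2 ratio of -0.37. On the arrays with Scriptaid labelled in Cy3 their mean was 0.24 (camera adjusted p = 0.000546) and on those with Scriptaid labelled in Cy5 it was -0.97 (adjusted p = 1.26e-06), both at the preset correlation, and over all arrays the list had an adjusted p = 0.290 with an estimated correlation. Spots at the scanner's ceiling are a candidate cause, since the 26 genes saturated everywhere moved alike, at 0.41 and -1.44. More ribosomal protein mRNA with the drug labelled Nullscript is argued against as the sole cause, since the mean turned to 0.24 in 1 dye orientation. Without saturated probes, where a member with another probe is measured by that one, the list was not called (camera adjusted p = 0.521). A contribution of such mRNA stays open, because saturated spots measure no fold and only 1 member was never saturated by its brightest probe.

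Of the 5 kidney lists all but the proximal tubule, and the stromal, endothelial and macrophage lists, were called higher in the channel labelled Scriptaid (each adjusted p = 0.290 with an estimated correlation). A larger share of only 1 cell type there is argued against, because 8 of the 10 cell type lists had a median above 0 in all 3 replicates. The neuronal list (median -0.16) and the red blood cell list (median -0.07) went the other way. The count does not address a smaller share of those types or a larger share of several types, which stay open. Several kidney lists also belong to 1 lineage, so the lists are not all separate cell types. The loess curve is argued against as the cause as well, because all 7 cell type lists called higher in the channel labelled Scriptaid were called so with median centring and no loess, at the preset correlation; after loess each had adjusted p = 0.290 with an estimated correlation. An effect of the drugs on expression in several cell types remains a possible explanation, which was not tested.

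Other ways to assign the drugs were limited to 4, which turn none or 1 of the 3 replicates, too few for a share under 0.05. The real assignment gave 5966 and 6290 genes, and each of the others gave 0. For the gene lists the real assignment gave 19 and the highest other 12. In each of these comparisons only 1 assignment, the real one, gave a result as large.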

How the results depend on the processing

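The alternative without saturated probes was chosen after seeing the data, and the others before. The counts of genes per direction stayed within 1.5 times, between 4571 and 6371 for the channel labelled Scriptaid and between 4376 and 8044 for the other, under other normalisations, filters, probe rules, moderation, the blocks, each dye orientation alone and an adjusted p under 0.01. At least 2-fold gave 449 and 355. Without each replicate in turn the counts ran from 4329 to 5698 and from 4002 to 5701. Of these only the 4002 without replicate 3 left the 1.5 times, and fewer replicates are the construction of that range. The replicate block with a dye coefficient gave 6302 and 6549, and with the drug alone 6326 and 6630. Aquantile after loess leaves ratios as they were and tests nothing. No scaling moved the median of all genes by over 0.1. The share of calls higher in the channel labelled Nullscript ran from 49.4% to 56.2% over the scalings, against 51.3%. Every scaling centres the ratios of an array near 0, so these values cannot show a shift of all genes. Before loess, the median log2 ratio of Cy5 over Cy3 was 0.87 to 1.51 with Scriptaid labelled in Cy5. It was 0.38 to 0.49 with Scriptaid labelled in Cy3, and a shift of all genes was not tested.

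The 19 list calls became 0 with an estimated correlation, and between 16 and 23 under the other alternatives. In fry, which tests each list by itself against no change, all lists but the renin-angiotensin and hypoxia lists passed. The HDAC list passed there with a mean of -0.00231 against the direction of camera (adjusted p = 0.0114). The probes with a dye effect at adjusted p < 0.05 numbered 24155 with median centring, no loess, which leaves the dye curve in place, and 826 without probes saturated on any array. With only the arrays with Scriptaid labelled in Cy3, the ribosomal list turned to 0.24, and Rpl8, Rpl13, Rpl27 and Rpl32 to 0.41 each, Cdkn1c to 0.17, Hba-a1 to 0.33, Hbb-bt to 0.25 and Pgk1 to 0.10, all saturated on some arrays, where a ratio at the ceiling measures no fold. Without saturated probes Rpl13, by another probe, turned to 0.14. The replicate block with the drug alone ended the calls of Cdkn1c, Hba-a1, Hbb-bt, Pgk1, Rpl8, Rpl13, Rpl27 and Rpl32 and of the red blood cell list, and the block with a dye coefficient added Pax2. The replicate blocks changed no other call of a list or named gene. The slide block ended the calls of Osr1 (limma adjusted p = 0.115), P4ha1 (adjusted p = 0.101) and Pdk1 (adjusted p = 0.0590), and changed no list call. The gene list: apoptosis regulators passed with median centring, no loess (adjusted p = 0.0443). Of the gene list: podocytes, the call was lost with probes well above background on all 6 arrays in both channels (adjusted p = 0.0510). Of 2425 values of 128 named genes, 2385 kept the call and, where called, the side, 29 lost the call, 2 gained it and 9 turned. A value called in neither fit counts as kept even where its sign differs, as for Pax2, whose lowest ratio was -0.02. For the 25 lists it was 480, 36, 7 and 2 of 525. There the side is that of the set test and not the sign of the mean, which for the HDAC list ran from -0.02 to 0.06. The cause was not tested where none is given. Few dim genes passed at 2-fold or more: of the 6606 genes with the lowest signal, 8 and 10 did so, against 179 and 112 of as many with the highest.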

Other observations

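The gene families and single genes of this part were chosen after their values were seen. Among families sharing a symbol stem with at least 15 measured genes, 120 in all, the zinc finger genes named Zfp were the largest with a shift; the ribosomal protein families are left out because most members were saturated. Of 339, 174 were higher in the channel labelled Scriptaid and 53 in the channel labelled Nullscript, with a median log2 ratio of 0.16 (camera adjusted p = 2.97e-05, and adjusted p = 0.794 with an estimated correlation). Of 22 beta protocadherin genes, which encode adhesion proteins from a gene cluster and have near-identical copies, 13 were higher in the channel labelled Scriptaid and none in the other (camera adjusted p = 0.000759, and adjusted p = 0.794 with an estimated correlation), among them Pcdhb22 with 1.38 and Pcdhb20 with 1.12. The secreted metalloproteinase genes named Adamts, with 11 of 16 higher in the channel labelled Scriptaid and 2 in the other (camera adjusted p = 0.0251, and adjusted p = 0.794 with an estimated correlation), included Adamts9 with 1.25 and Adamts5 with 1.18. Of 82 genes whose symbols begin with Atp, 42 were higher in the channel labelled Nullscript and 11 in the other, with a median of -0.14 (camera adjusted p = 0.0251, and adjusted p = 0.794 with an estimated correlation), and 11 of the 82 were saturated on some array. Among the 22 subunits of the V-ATPase, the proton pump of acidic organelles, which were not tested as a set, 10 were higher in the channel labelled Nullscript, 1 in the other and 11 did not pass, with Atp6v1c2 at -1.37 and Atp6v1a at -0.84.

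Xist, the RNA of the inactive X chromosome, had a log2 ratio of 0.50 ± 0.08 (SE, n = 3), and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0.51, 0.30, 0.22 and 0.53. All 5 were higher in the channel labelled Scriptaid in each of the 3 replicates. Of 886 olfactory receptor genes, 137 were higher in the channel labelled Nullscript and 5 in the other, with a median of -0.03, and the family did not pass (camera adjusted p = 0.102).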
